A study of Mus musculus with 6 samples.

How the data were processed

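RNA sequencing libraries were made from inguinal white adipose tissue of mice on a high-fat diet, 3 wild type and 3 Mpst knockout. Per the labels' protocols, total RNA was extracted with TRIzol, libraries were prepared with the TruSeq RNA v2 kit, which does not mark strand, and reads of 75 bp were sequenced single-end on a NextSeq500. The submitters' processing notes name HISAT2 2.1.0, an aligner, HTSeq 0.13.5, a read counter, DESeq2 1.26 and the mouse build mm10. The annotation and the settings of the counter are not given in the sources used here. The deposited values are whole-number counts per gene symbol, not normalised, for 24984 genes, and each deposited file ends with summary lines of the counter. Reads that the counter assigned to no feature, one of these lines, made up 8.85% to 14.7% of the reads that were placed uniquely, and ambiguous reads 1.63% to 1.83%. Without the settings, it is not known whether reads of the first kind lie within or outside genes. The lines for reads not aligned and not placed uniquely held 713158 to 4071968 and 1083925 to 3396317. Summary lines were left out of library sizes and tests. Counting leaves out reads that match several places, so genes with near-identical paralogs or pseudogenes, and overlapping or antisense genes, are uncertain.

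Each deposited count file was assigned to its sample and each sample to its genotype from the labels. Sequencing depth ranged from 8054560 to 22458630 counts per library, and precision for genes of few counts is limited most in knockout replicate 1. Replicates of a group differed by more than sampling noise in every pair (median ratio to sampling noise 3.08 to 21.4 over genes with at least 50 counts per pair), so no library was counted as a copy of another.

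Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 14065, libraries were scaled by the trimmed mean of M-values, and genotypes were compared with a robust quasi-likelihood F test without covariates, all 6 libraries in the fit. P-values were adjusted by the Benjamini-Hochberg method over all tested genes and called under 0.05. The standard error is the log2 fold change divided by the square root of F. CPM values are counts scaled to the normalised library size, with mean and SD over 3 libraries. The common biological coefficient of variation was 19.5%. Counts were simulated for this comparison from the real means and library sizes, in 3 runs of 14065 genes. In each run 200 genes were changed 2-fold or 4-fold and a further 40 by less. The test recovered 61.3% of the 2-fold and 93% of the 4-fold changes, with 8.08% false calls. Genes were drawn independently, without effects that a library shares across genes, so these rates may not hold for the real libraries.

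Before the data were examined, 31 gene lists were written from textbook knowledge (pathways of sulfur, mitochondrial and lipid metabolism, cell type markers, stress and proliferation genes, and genes near Mpst). The 29 lists with at least 3 tested members were tested two-sided with camera (preset correlation 0.01) and adjusted over the lists. At that setting 5 lists were higher and 8 lower. None passed with an estimated correlation, and fry, which tests whether the members of a list move on balance one way without comparing them with other genes, passed 1 list, the sulfur enzymes, in its directional test and 23 lists in its mixed test. The sulfur list holds the deleted gene, and without Mpst its directional adjusted p was 0.0357 over 14 members. Members adjusted over the list alone were counted separately. The principal components used log2 CPM with a prior count of 2.

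The rule for genes named in the text was also fixed before the data were examined. It takes Mpst, the 8 largest increases and 8 largest decreases among called genes whose libraries do not overlap between groups, whose mean reaches 5 CPM in the higher group and whose symbol is not that of a predicted gene, the 2 called members with the smallest p from each list (or the 1 with the smallest p, by its values, where none is called), and any member of the sulfur list. Not every gene that the rule takes is given in the text. Other names are said to be chosen after their values were seen. Positions, exon lengths and GC content came from GENCODE release M21 on GRCm38, the assembly behind mm10, matched by gene symbol for 13933 of the tested genes.

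Alternatives fixed before the data were examined were size factors by relative log expression, upper-quartile scaling, DESeq2 1.42.0, limma-voom (limma 3.58.1), no low-count filter, a minimum of 10 CPM on average, the replicate number as a block, each library left out in turn, a fit without robust estimation, a test against a 1.5-fold change, and for lists an estimated correlation and fry. Alternatives added after seeing the data left out Rn45s and Malat1, thinned all libraries to the smallest, left out the 2 libraries highest in muscle transcripts, took the trend of each library on GC content and length out through an offset, and left Mpst out of its list.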

Results

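Bulk RNA sequencing measured transcript levels in inguinal white adipose tissue, a subcutaneous fat depot, from mice fed a high-fat diet. The 6 libraries fell into 2 genotypes, wild type (n = 3) and Mpst knockout (n = 3). The total number of reads counted in genes was 17394489, 17793003 and 21576075 in wild-type replicates 1, 2 and 3 and 8054560, 22458630 and 21565825 in knockout replicates 1, 2 and 3. Between 16143 and 17395 of the 24984 listed genes had at least 1 count in a library. The labels name replicates but do not say that they are separate animals, so the p-values measure the spread between these samples, which may be technical. Principal component 1 of the 500 most variable genes held 47.9% of their variance and placed the wild-type libraries at −6.49, −13.9 and −30.2 and the knockout libraries at 19.3, 17.7 and 13.6. The comparison of the genotypes addresses how adipose tissue under a high-fat diet differs when MPST, a mitochondrial and cytosolic sulfurtransferase that makes hydrogen sulfide from cysteine breakdown products, is missing.

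Mpst was nearly absent from the knockout libraries. Its normalised count was 81.1 ± 5.01 CPM (counts scaled to the library size) in wild type (SD, n = 3) and 0.393 ± 0.042 CPM in knockout (SD, n = 3). The log2 fold change was −7.63 (SE 0.17, adjusted p = 1.33e-07). The raw counts were 1358, 1394 and 1624 in the wild-type libraries and 3, 10 and 9 in the knockout libraries, so every library matched its genotype label. Mpst (ENSMUSG00000071711.12) lies on chromosome 15 from 78406416 to 78414013 on the plus strand of GRCm38. Which exons the allele removes is not given in the sources used here. Its neighbour Tst, which encodes the related sulfurtransferase rhodanese, starts 509 bases from the start of Mpst on the opposite strand, so that the genes lie head to head. Tst stood at 48.7 ± 22.5 CPM in wild type and 26.7 ± 1.44 CPM in knockout (log2 fold change −0.87, SE 0.28, adjusted p = 0.0857).

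Of the 15 tested members of the list of sulfur amino acid and hydrogen sulfide enzymes, 5 fell and none rose, and 7 fell and 1 rose when adjusted over the list alone. Beside Mpst, Selenbp1, a methanethiol oxidase, fell from 159.8 ± 15.5 to 95.8 ± 9.95 CPM (log2 fold change −0.74, adjusted p = 0.0207). Sqor, the mitochondrial sulfide quinone oxidoreductase, fell from 154 ± 32.8 to 89.2 ± 3.12 CPM (−0.79, adjusted p = 0.0286). Cbs, cystathionine beta-synthase, fell by 0.95 on the log2 scale (adjusted p = 0.0311), and Txn2, the mitochondrial thioredoxin, fell by 0.51 (adjusted p = 0.0469). Cth, the other transsulfuration enzyme, stood at 9.78 ± 3.40 CPM in wild type and 16.1 ± 1.30 CPM in knockout (log2 fold change 0.72, adjusted p = 0.0919). Cdo1, cysteine dioxygenase, stood at 1073.5 ± 155 and 724 ± 9.20 CPM (−0.57, adjusted p = 0.0541). Tst, Cth and Cdo1 were called with DESeq2, Tst and Cth also without wild-type replicate 1, and Cdo1 also without wild-type replicate 3. With each library left out, their log2 fold changes ranged from −1.09 to −0.42, 0.54 to 1.04 and −0.68 to −0.48. Tstd1, Ethe1, Suox, Csad, Got1, Got2 and Txn1 had log2 fold changes between −0.42 and 0.40, with adjusted p from 0.156 to 0.979. For the whole list the median log2 fold change was −0.42. Camera, a competitive gene set test, gave an adjusted p of 4.59e-11, against an adjusted p = 0.0541 with an estimated correlation. Without Mpst itself the median over 14 members was −0.42 and the adjusted p 0.00080, against an adjusted p = 0.396 with an estimated correlation. Over 18 settings camera's adjusted p for the list ranged from 6.99e-12 to 0.00080. The upper end is the list without Mpst in the main fit, a setting that is also counted among the refits of the other lists. The macrophage list had a median log2 fold change of 0.997 in the same libraries.

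**Figure D1:**
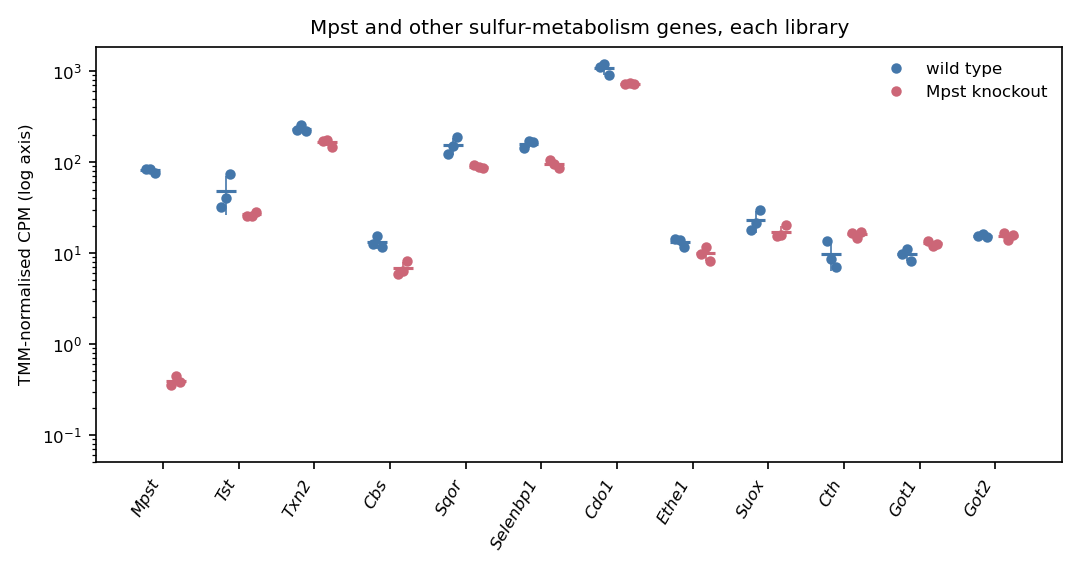
Normalised CPM (logarithmic axis) of Mpst and 11 other genes of sulfur metabolism in each of the 3 wild-type and 3 knockout libraries, with points for libraries, horizontal lines for means and vertical lines for 1 SD. Mpst stood at 75.4 to 84.7 CPM in wild type and 0.358 to 0.440 CPM in knockout.

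Among called genes that reached 5 CPM and whose libraries did not overlap between groups, Gdf3, a ligand of the TGF-beta family, rose most, from 0.388 ± 0.255 to 6.57 ± 1.68 CPM, a 17.04-fold change (log2 4.09, SE 0.44, adjusted p = 0.0119). Rnf128, an E3 ubiquitin ligase, rose 12.0-fold. Clec4d, a C-type lectin receptor of myeloid cells, rose 8.21-fold and Rgs1, a regulator of G-protein signalling in leukocytes, 7.96-fold. Il1rn, the interleukin-1 receptor antagonist, rose 7.29-fold, from 1.64 ± 1.07 to 11.7 ± 0.976 CPM. Olfr1372-ps1, an olfactory receptor pseudogene locus, rose 6.74-fold, Cck, the peptide hormone cholecystokinin, 6.73-fold, and Il7r, the interleukin-7 receptor, 6.19-fold. Adjusted p for these 8 genes lay between 0.0119 and 0.0271. Without wild-type replicate 1 the rise was 26.6-fold for Gdf3, 20.2-fold for Rnf128 and 14.2-fold for Rgs1, and without wild-type replicate 3 it was 7.94-fold for Rnf128 and 10.3-fold for Olfr1372-ps1. Among the decreases, Orm3, an acute-phase orosomucoid, was 8.58-fold lower (6.85 ± 2.75 against 0.750 ± 0.239 CPM). Cfd, the adipocyte-secreted complement factor adipsin, fell from 9710 ± 3667 to 2324 ± 277 CPM, 4.18-fold lower (log2 −2.06, SE 0.28, adjusted p = 0.0144). The nuclear long non-coding RNA Malat1 was 4.94-fold lower, albumin (Alb) 4.17-fold, Prtn3, a neutrophil serine protease, 4.15-fold, and the secretin receptor Sctr 4.10-fold. The cytochrome P450 Cyp2e1 was 3.78-fold lower (609 ± 147 against 161 ± 82.6 CPM) and the interleukin-17 receptor family member Il17re 3.59-fold. Adjusted p for these 8 genes lay between 0.0119 and 0.0315. Without wild-type replicate 3, Prtn3 was 2.75-fold, Sctr 2.65-fold and Il17re 2.39-fold lower. Prtn3 ends at 79883174 on chromosome 10 and Cfd starts at 79890853 on the same strand. Orm3 belongs to a family of near-identical copies, and its count is uncertain where reads could be shared.

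Of 14065 genes tested with edgeR's quasi-likelihood test, 669 were higher and 373 lower in the knockout at an adjusted p under 0.05, of which 266 and 83 changed at least 2-fold. At an unadjusted p under 0.05 there were 3878 genes, against 703 with no effect. The groups did not overlap in 33.3% of the tested genes, against 10% by chance. The share of higher calls was 64.2%, against 53.9% with DESeq2 (1026 higher and 877 lower) and 50.3% with the trend of each library on GC content and length taken out (389 and 384). The higher and lower counts changed with single libraries, to 538 and 263 without wild-type replicate 1, 0 and 1 without replicate 2, and 1434 and 1167 without replicate 3. They were 41 and 5 without knockout replicate 1, 1 and 1 without replicate 2, and 1 and 2 without replicate 3. Every called gene that kept a value kept its direction in these fits. The groups did not overlap in any of the 1042 called genes, so leaving out a library could hardly reverse a direction, and this adds no support. Of the called genes named by the rule, Mpst kept its call in all 6 of these fits. The other 56 lost theirs without wild-type replicate 2 and without knockout replicate 2, and 55 of them without knockout replicate 3, Cyp2e1 being the exception. Without knockout replicate 1, 49 lost theirs, without wild-type replicate 1, 12 did, and without wild-type replicate 3, Cyp2e1 did.

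**Figure D2:**
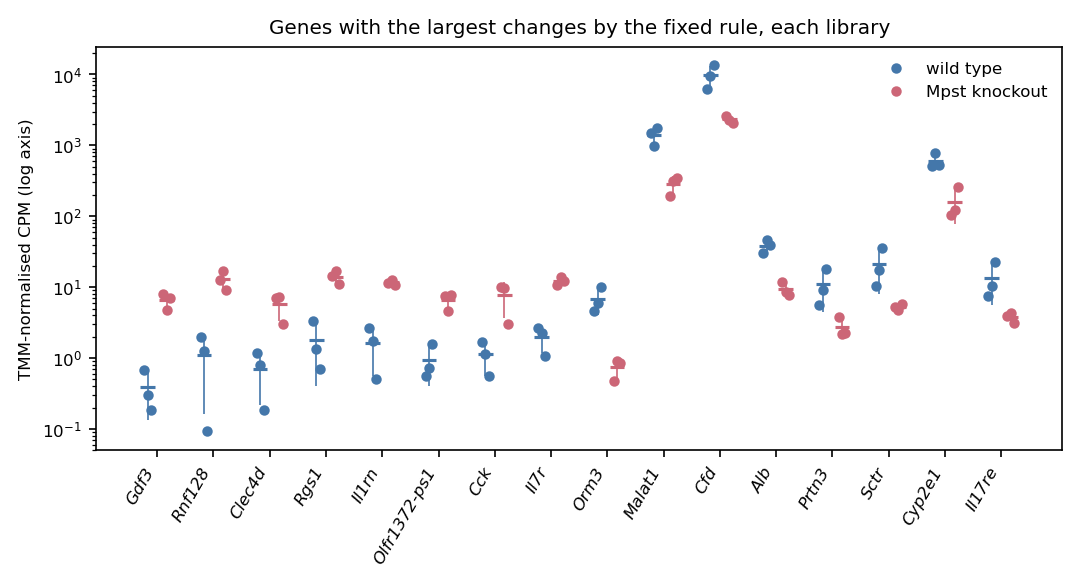
Normalised CPM (logarithmic axis) of the 8 genes with the largest called increase and the 8 with the largest called decrease by the fixed rule, in each of the 3 wild-type and 3 knockout libraries, with points for libraries, horizontal lines for means and vertical lines for 1 SD. Cfd went from 9710 to 2324 CPM and Gdf3 from 0.388 to 6.57 CPM, and the groups do not overlap in any of these genes.

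Of 74 tested nuclear-encoded subunits of oxidative phosphorylation, 16 fell and none rose, and 53 fell and none rose when adjusted over the list alone. Among them were the complex I subunits Ndufa7 (254 ± 14.0 against 157 ± 29.6 CPM, log2 fold change −0.70, adjusted p = 0.0342) and Ndufb2 (181 ± 12.2 against 108 ± 24.0 CPM, −0.75, adjusted p = 0.0344). The median was −0.52, with 71 members below 0 (camera adjusted p = 7.03e-20, against an adjusted p = 0.471 with an estimated correlation). Its mean relative to the wild-type mean was 0.00, 0.08 and −0.09 in the wild-type libraries and −0.49, −0.27 and −0.71 in the knockout libraries. In the same libraries the macrophage list had a median log2 fold change of 0.997. Of 39 components of mitochondrial protein import, 5 fell and none rose, and 12 fell and none rose when adjusted over the list alone. Timm50, the receptor subunit of the inner-membrane translocase, fell from 111 ± 6.97 to 76.5 ± 9.04 CPM (−0.54, adjusted p = 0.0398). The others were Timm8b, an intermembrane-space chaperone (−0.63, adjusted p = 0.0413), Samm50 of the outer-membrane sorting machinery (−0.48), Dnajc15 (−0.57) and the inner-membrane peptidase Immp2l (−0.62). Members of a list named beyond the 2 with the smallest p were chosen after their values were seen. The import list had a median of −0.26 (camera adjusted p = 0.00037, against an adjusted p = 0.679 with an estimated correlation). Its mean per library overlapped between the groups, at −0.13 in wild-type replicate 3 and −0.09 in knockout replicate 2. The adjusted p was 0.172 without the 2 libraries highest in muscle transcripts, in a range of 1.19e-05 to 0.172 over 18 refits, and the median was −0.17 without knockout replicate 3.

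Of 78 mitochondrial ribosomal protein genes, Mrps15 (−0.71, adjusted p = 0.0269), Mrps16 (−0.66, adjusted p = 0.0398), Mrps18c (−0.63) and Mrps30 (−0.46) fell and none rose. No member passed edgeR's test when adjusted over the list alone, while 42 were lower at an unadjusted p under 0.05, 14 by DESeq2 and 5 by limma-voom. Their median was −0.37 (camera adjusted p = 3.90e-11, against an adjusted p = 0.606 with an estimated correlation). None of the 79 cytosolic ribosomal protein genes passed edgeR's test, over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 42 were lower, and 22 were lower by DESeq2 and none by limma-voom. Rps21, with the smallest p, stood at 601 ± 93.9 and 341 ± 98.7 CPM (log2 fold change −0.82, adjusted p = 0.0585) and was called without wild-type replicate 3 (−0.92), with DESeq2 and with no low-count filter. The 79 genes had a median of −0.45 (camera adjusted p = 6.62e-14, against an adjusted p = 0.610 with an estimated correlation). Their mean per library overlapped between the groups, at −0.33 in wild-type replicate 3 and −0.20 in knockout replicate 2 relative to the wild-type mean. Ribosomal protein genes have many processed pseudogenes, and their counts are uncertain where reads could be shared. Transcripts of the mitochondrial genome could not be compared, since 0 of the 13 protein-coding symbols were listed.

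Tricarboxylic acid cycle genes did not pass as a list (22 tested, median −0.19, camera adjusted p = 0.236, and 0.0296 without wild-type replicate 1, in a range of 0.0296 to 0.762 over 18 refits). Their median ranged from −0.26 to −0.05 with each library left out. Dlat, a subunit of pyruvate dehydrogenase, rose from 114 ± 3.32 to 176 ± 13.6 CPM (log2 fold change 0.62, adjusted p = 0.0231) and was the only member called, also when adjusted over the list alone. In the list of mitochondrial biogenesis and dynamics (18 tested, median −0.09, camera adjusted p = 0.501), Gabpa, a transcription factor of nuclear genes for mitochondrial proteins, rose by 0.87 on the log2 scale (adjusted p = 0.0368) and Pink1, a mitophagy kinase, fell by 0.52 (adjusted p = 0.0448), with 1 higher and 2 lower when adjusted over the list alone.

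Of 20 adipocyte identity genes, 3 fell and none rose, and 4 fell and 1 rose when adjusted over the list alone. Beside Cfd these were Retn, which encodes resistin (2767 ± 382 against 1399.8 ± 222 CPM, log2 fold change −0.98, adjusted p = 0.0229), and Lipe, hormone-sensitive lipase (2460.0 ± 338 against 1517 ± 143 CPM, −0.70, adjusted p = 0.0415). The median over the list was −0.35 (camera adjusted p = 0.00226, against an adjusted p = 0.396 with an estimated correlation). Among its members chosen after their values were seen, Adipoq (−0.35, adjusted p = 0.240), Pparg (−0.17, adjusted p = 0.406), Cebpa (−0.36, adjusted p = 0.240) and Lep (0.22, adjusted p = 0.686) did not pass the test. Of 23 genes of fatty acid and triglyceride synthesis, 2 fell and none rose, and 4 fell and none rose when adjusted over the list alone. They were Thrsp, a regulator of lipogenesis (809 ± 164 against 297 ± 59.6 CPM, −1.44, adjusted p = 0.0149), and Aacs, acetoacetyl-CoA synthetase (−0.60, adjusted p = 0.0425). Their median was −0.21 (camera adjusted p = 0.0188, against an adjusted p = 0.396 with an estimated correlation). That call ended in the fit of genes with at least 10 CPM on average (adjusted p = 0.0578, range 0.00338 to 0.0578 over 18 refits). Of 23 genes of branched-chain amino acid breakdown, 3 fell and none rose, and 8 fell and none rose when adjusted over the list alone. Bcat2, the mitochondrial branched-chain aminotransferase, fell from 268 ± 28.1 to 157 ± 4.04 CPM (−0.77, adjusted p = 0.0158), with Hsd17b10 (−0.78, adjusted p = 0.0173) and Bckdha, a subunit of the branched-chain ketoacid dehydrogenase (−0.71). Their median was −0.29 (camera adjusted p = 0.00011, against an adjusted p = 0.606 with an estimated correlation), and −0.11 without wild-type replicate 3. In the same libraries 8 of 22 macrophage genes rose, with a median of 0.997 over that list.

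The lists of lipolysis and lipid droplet (16 tested, median −0.30, camera adjusted p = 0.0913), fatty acid oxidation (21 tested, median −0.06, adjusted p = 0.412) and thermogenic adipocyte genes (17 tested, median 0.14, adjusted p = 0.827) did not pass. With each library left out, their medians ranged from −0.36 to −0.15, −0.14 to −0.01 and −0.02 to 0.35. The lipolysis list passed without wild-type replicate 1 (adjusted p = 0.0109, range 0.0109 to 0.243 over 18 refits). Lipe was its only called member, with 2 higher and 2 lower when adjusted over the list alone. In the list of fatty acid oxidation, Cpt1a, which controls fatty acid entry into mitochondria, rose from 78.3 ± 13.1 to 133 ± 5.33 CPM (log2 fold change 0.76, adjusted p = 0.0237), with 1 higher and 1 lower when adjusted over the list alone. Cox8b, a cytochrome oxidase subunit of brown fat and muscle, fell by 1.02 on the log2 scale (adjusted p = 0.0244) and was the only thermogenic member called, also when adjusted over the list alone. Ucp1, the uncoupling protein of brown and beige fat, had raw counts of 4, 0 and 9 in wild type and 5, 29 and 12 in knockout. Scaled to library size these were 0.245, 0 and 0.418 CPM against 0.596, 1.28 and 0.509 CPM. The gene was not called (log2 fold change 1.78, SE 0.74, edgeR adjusted p = 0.160), and its counts are low.

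Of 22 macrophage genes, 8 rose and none fell, and 18 rose and none fell when adjusted over the list alone. Gpnmb, a glycoprotein of lipid-laden macrophages, rose 5.60-fold from 30.5 ± 10.99 to 170.5 ± 38.2 CPM (log2 2.48, SE 0.28, adjusted p = 0.0119), and Itgam, the integrin CD11b, 2.93-fold from 9.35 ± 1.48 to 27.2 ± 3.38 CPM (1.55, SE 0.17, adjusted p = 0.0119). The others, chosen after their values were seen, were Adgre1, Ctss, Clec7a, Fcgr1, Mrc1 and Cd68, with log2 fold changes from 0.79 to 1.83. The macrophage list had a median of 0.997 (camera adjusted p = 1.07e-14, against an adjusted p = 0.396 with an estimated correlation). Its mean relative to the wild-type mean was 0.48, 0.22 and −0.70 in the wild-type libraries and 1.21, 1.41 and 1.25 in the knockout libraries. Of 17 inflammatory cytokine and chemokine genes, 5 rose and none fell, and 6 rose and none fell when adjusted over the list alone. These were Il1rn, Ccl3 (log2 fold change 1.88, adjusted p = 0.0360), Cxcl10 (1.29), Ccl4 (1.34) and the receptor gene Tlr2 (0.88). Their median was 0.46 (camera adjusted p = 0.00035, against an adjusted p = 0.396 with an estimated correlation). The call ended among genes with at least 10 CPM on average (adjusted p = 0.0975, range 3.41e-06 to 0.0975 over 18 refits).

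Of 15 T cell genes, 1 rose and none fell, and 3 rose and none fell when adjusted over the list alone. It was Themis, a regulator of T cell development (0.353 ± 0.204 against 1.49 ± 0.280 CPM, log2 fold change 2.02, adjusted p = 0.0381). Their median was 1.15 (camera adjusted p = 7.25e-05, against an adjusted p = 0.471 with an estimated correlation). The mean of the T cell genes relative to the wild-type mean was −0.24, −0.04 and 0.28 in the wild-type libraries. It was 0.38, 1.07 and 1.53 in the knockout libraries, so knockout replicate 1 lay close to wild-type replicate 3. Of 11 B cell genes, Cd22 rose by 2.102 on the log2 scale (adjusted p = 0.0370) and none fell, with 1 higher when adjusted over the list alone, and Cd22 rose by 2.88 without wild-type replicate 1. The B cell list did not pass (median 0.35, camera adjusted p = 0.179), but did without wild-type replicate 1 (median 0.60, adjusted p = 0.00861), while the median was 0.10 without wild-type replicate 3 (adjusted p range 0.00861 to 0.822 over 17 refits). Of 27 extracellular matrix genes, 6 rose and none fell, and 7 rose and none fell when adjusted over the list alone. Thrombospondin-1 (Thbs1) rose from 26.3 ± 5.25 to 65.8 ± 9.02 CPM (1.32, SE 0.17, adjusted p = 0.0128). The matrix list's median was 0.36 (camera adjusted p = 9.37e-06, against an adjusted p = 0.471 with an estimated correlation), and 0.22 without wild-type replicate 3. None of 15 cell cycle genes passed edgeR's test, over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 1 was higher, and none passed with DESeq2 or limma-voom. Kif11, with the smallest p, stood at 3.35 ± 1.34 and 5.63 ± 1.51 CPM (0.77, adjusted p = 0.164). The cell cycle list had a median of 0.47 (camera adjusted p = 0.0237, against an adjusted p = 0.837 with an estimated correlation). Its mean per library overlapped between the groups, at 0.57, −0.09 and −0.48 in wild type and 0.31, 0.44 and 0.64 in knockout. The adjusted p was 0.0545 without wild-type replicate 2, 0.375 without wild-type replicate 3 (median 0.22), 0.0851 without knockout replicate 3, 0.173 without the 2 libraries highest in muscle transcripts and 0.189 among genes with at least 10 CPM on average, in a range of 1.12e-05 to 0.375 over 18 refits.

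**Figure D3:**
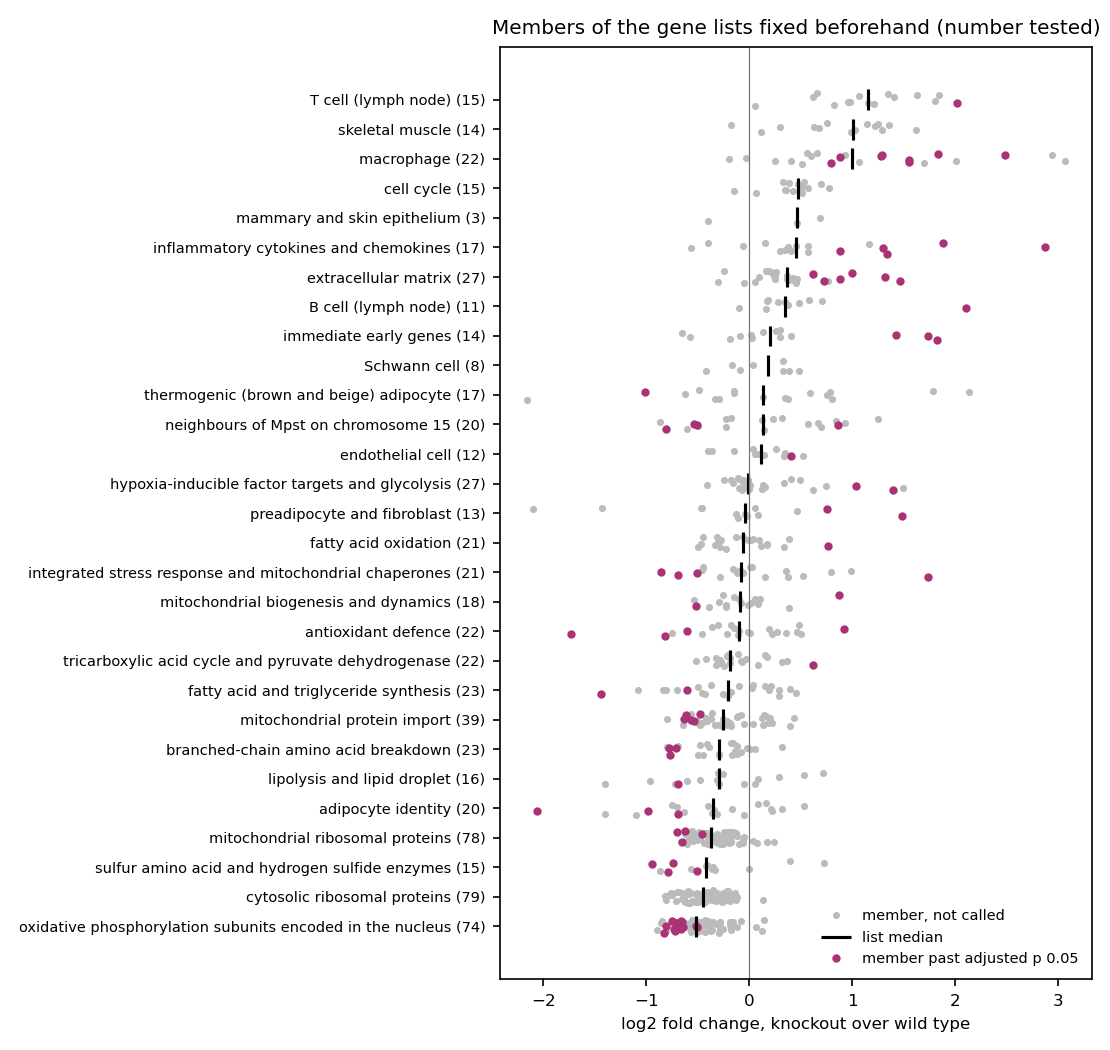
Log2 fold change (knockout over wild type) of each tested member of the 29 gene lists with at least 3 tested members, with called members in purple, the others in grey and the list median as a black bar. Mpst at −7.63 is left out of the points but counts in the median of its list, and the medians run from −0.52 for oxidative phosphorylation to 1.15 for T cell genes.

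Among stress genes, Hif1a, the oxygen-regulated transcription factor, rose from 38.3 ± 11.02 to 101 ± 12.4 CPM (log2 fold change 1.40, SE 0.20, adjusted p = 0.0149) and Ddit4, an inhibitor of mTOR signalling, rose by 1.04 (adjusted p = 0.0351). They were the only called members of 27 hypoxia-inducible factor target and glycolysis genes, also when adjusted over the list alone, and the list did not pass (median −0.01, mean 0.19, camera direction up, adjusted p = 0.239). The list of the integrated stress response and mitochondrial chaperones did not pass (21 tested, median −0.08, mean 0.03, camera direction down, adjusted p = 0.412). In it Atf3, a stress-induced transcription factor, rose by 1.73 (adjusted p = 0.0238). Phgdh, the entry enzyme of serine synthesis (404 ± 62.6 against 223 ± 19.1 CPM, −0.86, adjusted p = 0.0191), the mitochondrial protease Clpp (−0.69) and asparagine synthetase Asns (−0.51) fell. When adjusted over the list alone, 3 were higher and 5 lower. The antioxidant list did not pass either (22 tested, median −0.11, camera adjusted p = 0.247). The secreted glutathione peroxidase Gpx3 (730.5 ± 328 against 219 ± 16.3 CPM, −1.74, adjusted p = 0.0174), superoxide dismutase Sod1 (−0.82, adjusted p = 0.0238) and Gpx1 (−0.61) fell. Haem oxygenase Hmox1 (0.92) rose, with 2 higher and 4 lower when adjusted over the list alone. Of 14 immediate early genes, Egr2 (1.42, adjusted p = 0.0174), Atf3 and Egr3 (1.82) rose, with 3 higher and none lower when adjusted over the list alone. The list's median was 0.20 (camera adjusted p = 0.0536, range 0.00102 to 0.317 over 18 refits), and it passed without wild-type replicate 3 (0.00563), knockout replicate 2 (0.0338) or knockout replicate 3 (0.0134), with no low-count filter (0.0270) and with GC content and length taken out (0.00102). With each library left out the median ranged from 0.0014, without knockout replicate 1, to 0.32, without wild-type replicate 3.

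Markers of other cell types were listed to show what else the tissue could hold. Among 12 endothelial genes, Vwf, von Willebrand factor, rose from 50.9 ± 1.16 to 67.3 ± 1.21 CPM (log2 fold change 0.40, adjusted p = 0.0467) and was the only call, also when adjusted over the list alone (median 0.11, camera adjusted p = 0.455). Among 13 preadipocyte and fibroblast genes, the matrix proteoglycans Dcn (0.76, adjusted p = 0.0313) and Lum (1.48, adjusted p = 0.0352) rose and none fell, with 3 higher and none lower when adjusted over the list alone. Their median was −0.04 and mean −0.15 (camera direction up, adjusted p = 0.827). No member of the lists of skeletal muscle (14 tested, median 1.01, camera adjusted p = 0.827), epithelium (3 tested, median 0.46, 0.827) or Schwann cell genes (8 tested, median 0.18, 0.674) passed edgeR's test over all genes, at an unadjusted p under 0.05, adjusted over the list alone, with DESeq2 or with limma-voom. In the muscle and epithelium lists the members with the smallest p were Myh2 (0.510 ± 0.243 against 0.809 ± 0.181 CPM) and Krt10 (6.04 ± 0.678 against 4.63 ± 0.772 CPM). The Schwann cell list passed without wild-type replicate 2 (adjusted p = 0.0469, range 0.00617 to 0.908 over 18 refits) and the muscle list without knockout replicate 3 (median −2.89, adjusted p = 0.0116, range 0.0116 to 0.915). The mean of the muscle genes relative to wild type was 2.26 in wild-type replicate 2 and 3.21 in knockout replicate 3, and −0.38 or lower in the other 4 libraries. Of the red blood cell list, Alas2 alone was tested (18.6 ± 6.93 against 12.3 ± 0.978 CPM, adjusted p = 0.176). It counts as 1 lower when adjusted over the list alone, a list of 1 tested gene, and was called without wild-type replicate 1 (−0.84). Among 20 genes neighbouring Mpst, 3 fell and 1 rose, and 5 fell and 6 rose when adjusted over the list alone. Ift27, an intraflagellar transport gene (35.4 ± 1.19 against 20.3 ± 3.18 CPM, −0.81, adjusted p = 0.0198), Kctd17 (−0.54) and Txn2 fell. Csf2rb2, a cytokine receptor subunit, rose (0.86, adjusted p = 0.0223). The median was 0.13 (camera direction down, adjusted p = 0.827).

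Some properties of the libraries moved with genotype. The 10 most abundant genes took 14.1 ± 0.162% of counts in wild type and 10.7 ± 0.580% in knockout, and the ribosomal RNA precursor Rn45s took 1.89 ± 1.23% and 0.348 ± 0.209% (each n = 3, exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). The share of uniquely placed reads that the counter assigned to no feature was 13.1 ± 1.76% and 10.4 ± 1.71% (n = 3, exact two-sided permutation p = 0.2). This share overlapped between the groups, at 11.2% in wild-type replicate 2 and 12.2% in knockout replicate 3. Across genes, which are not independent replicates, the log2 fold change had a Spearman correlation of −0.30 with GC content and 0.26 with exon length. With both trends taken out, the median was −0.41 for oxidative phosphorylation (16 members lower), −0.30 for mitochondrial ribosomal proteins (8 lower), −0.36 for cytosolic ribosomal proteins (2 lower) and 1.08 for macrophage genes (12 higher). Of the named genes, Prtn3, Sctr, Timm50, Timm8b, Aacs, Cox8b, Gabpa, Pink1, Themis, Vwf, Dcn, Lum and Txn2 were no longer called with that correction.

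**Figure D4:**
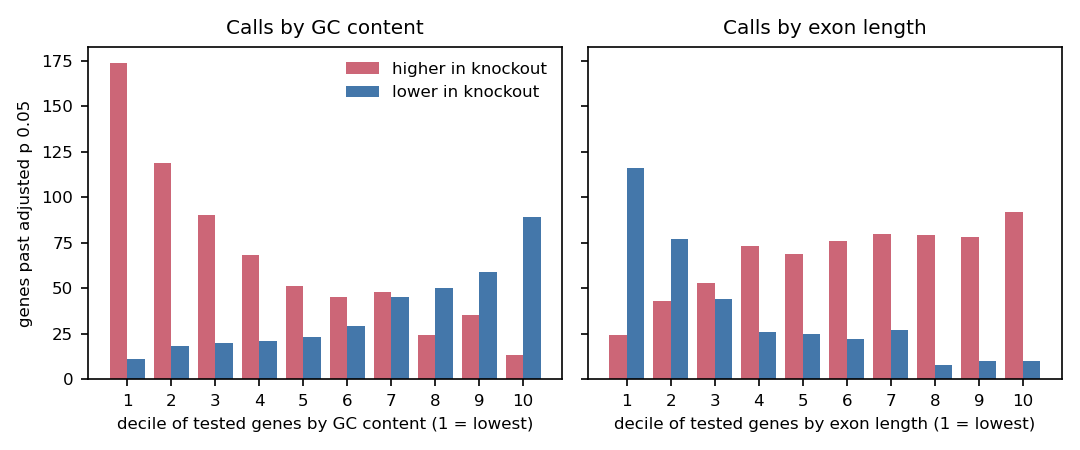
Number of genes higher (red) and lower (blue) in the knockout at an adjusted p under 0.05, by decile of the tested genes ranked by GC content (left) and by exon length (right). The decile with the lowest GC content held 174 higher and 11 lower genes and that with the highest held 13 and 89.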

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

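The corrections for GC content and length, thinning, the removal of Rn45s and Malat1, of the 2 libraries highest in muscle transcripts and of Mpst from its list were chosen after the results were seen. The log2 fold change of Mpst stayed past the threshold, from −7.73 to −7.58 with each library left out. The 669 higher and 373 lower genes stayed within 1.5 times with relative log expression, upper-quartile scaling, limma-voom, no filter, a minimum of 10 CPM, non-robust fits, thinning and without Rn45s and Malat1. They became 1026 and 877 with DESeq2, 11 and 5 against a 1.5-fold change, where fewer genes can pass by construction, and 389 and 384 with the GC and length correction. Leaving out each library in turn gave 0 to 1434 higher and 1 to 1167 lower genes. The fits without both muscle-rich libraries, wild-type replicate 2 and knockout replicate 3, gave 0 and 1, with 1118 and 770 at an unadjusted p under 0.05, 174 and 60 by DESeq2 and 0 and 1 by limma-voom. Without wild-type replicate 2 alone edgeR gave 0 and 1, with 1552 and 1194 unadjusted, 514 and 289 by DESeq2 and 0 and 1 by limma-voom. Fewer samples lower the power of these fits, but the cause of the difference between libraries was not tested. With the replicate number as a block there were 1387 and 1289 genes. Deviations of samples with the same number correlated at 0.17, −0.10 and 0.30, and not every sample correlated best with its own number. The main test did not treat the numbers as pairs, but correlations over 3 libraries per group cannot exclude a pairing. Of 29 lists, 13 passed camera, 9 to 16 in every refit (13 to 16 with each library left out), 0 with an estimated correlation and 1 with fry. The skeletal muscle list had a median of 1.01, not called, and −2.89, called lower, without knockout replicate 3, in a range of −2.89 to 3.61 with each library left out. DESeq2 and the 1.5-fold test give no list test. Depth limits knockout replicate 1 most, and thinning to it called 557 higher and 306 lower genes.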

Other observations

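The tests of the explanations below were all chosen after the results they bear on were seen. Of 21 tested genes of glutathione S-transferases, which conjugate glutathione to reactive compounds, 9 fell, none rose and 12 did not pass, with a median of −0.59. The family was picked because it stood out, and it was not tested as a group. The 9 kept their direction under both other scalings and with the GC and length correction. So did every called gene with a value in these fits, and this adds no support. Gsta4, which acts on lipid aldehydes, went from 43.2 ± 8.28 to 18.6 ± 1.23 CPM (SD, n = 3; log2 fold change −1.21, SE 0.16, edgeR adjusted p = 0.0129), Gstm1 from 339 ± 34.3 to 186 ± 15.2 CPM (−0.87, SE 0.13, adjusted p = 0.0153) and Gstt1 from 203 ± 66.3 to 101 ± 5.44 CPM (−1.02, SE 0.21, adjusted p = 0.0302). With GC content and length taken out, 8 members fell and the median was −0.52. Members of the alpha and mu classes are close paralogs and share reads, so single members are uncertain. The macrophage list had a median log2 fold change of 0.997 in the same libraries.

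Some single genes outside the lists were chosen after their values were seen and were not tested as a group. Lysosomal acid lipase (Lipa) rose from 63.6 ± 8.45 to 138 ± 11.7 CPM (log2 fold change 1.11, SE 0.14, edgeR adjusted p = 0.0119), the cholesterol ester hydrolase Nceh1 by 1.58 on the log2 scale (SE 0.18, adjusted p = 0.0119), the cholesterol-esterifying enzyme Soat1 by 1.36 (SE 0.27, adjusted p = 0.0264), the scavenger receptor Msr1 by 1.499 (SE 0.22, adjusted p = 0.0149), the tetraspanin Cd9 by 1.07 (SE 0.15, adjusted p = 0.0149) and osteopontin (Spp1) by 1.76 (SE 0.36, adjusted p = 0.0302). The innate receptors Tlr13 and Tlr8 rose by 2.20 and 2.06 (adjusted p = 0.0107 and 0.0119). The taurine transporter Slc6a6 rose from 36.4 ± 2.97 to 95.6 ± 12.1 CPM, and the peroxisomal membrane protein Pxmp2 fell from 109 ± 11.5 to 41.1 ± 4.85 CPM (adjusted p = 0.0107 for both).

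With 10 splits of the 6 libraries into 3 and 3, no share under 0.05 can be had. The real split gave 669 higher and 373 lower genes, and 1 of the 10 splits, the real one, gave as many. The highest of the others gave 0 with edgeR (102 to 1209 genes at an unadjusted p under 0.05, 0 to 47 with DESeq2 and 0 with limma-voom). For the gene lists, the real split gave 13 and the highest of the others 17, and 4 of the 10 splits, the real one included, gave 13 or more.

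Oxidative phosphorylation, mitochondrial ribosomal and cytosolic ribosomal transcripts had medians of −0.52, −0.37 and −0.45, and the calls of all 3 lists were lost with an estimated correlation (adjusted p = 0.471, 0.606 and 0.610). The trend of each library on GC content and transcript length, as fitted here, did not account for the whole shift. An effect of these properties that the fitted trend does not follow was not tested. After both trends were taken out the medians were −0.41, −0.30 and −0.36, against −0.06 over all genes, and the upper quartiles stayed below 0 (−0.26, −0.18 and −0.21). Part of the shift was shared by like genes. Without the correction, 10000 lists matched by GC content, exon length and level had middle medians of −0.20, −0.09 and −0.20. A lower share of adipocyte RNA that leaves the other cell types unchanged would raise their markers alike, but the upper quartiles of the endothelial genes (0.34) and of the preadipocyte genes (0.08) lay below the lower quartile of the macrophage genes (0.57). An increase of macrophages in place of adipocytes stays open, as does a difference of genotype in the adipocytes, which was not tested apart from it. The adipocyte identity genes moved unequally, with a median of −0.35, quartiles of −0.71 and 0.10, 14 below 0 and 6 above. These quartiles enclose the oxidative phosphorylation median, so the adipocyte genes cannot decide this. The hypothesis of lower respiratory chain transcripts per adipocyte would need sorted cells.

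Macrophage transcripts had a median of 0.997 (camera adjusted p = 1.07e-14, against 0.396 with an estimated correlation), the most abundant being Lyz2 (374 ± 132 against 712 ± 15.05 CPM, edgeR adjusted p = 0.0572) and Lgals3 (322 ± 135 against 673 ± 140 CPM, 0.0716), while C1qa, next in level, stood at 255 ± 81.3 and 302 ± 37.4 CPM (0.518). The low level of wild-type replicate 3 is not the whole source, since without it the median was 0.83. More macrophages of a uniform kind, with unchanged expression in each, would raise all members by about the same amount. Of the 22 members, 13 differed from the list median by over 2 of their own standard errors, which leaves out the error of the median. More cells of a subset that expresses the members unequally would also raise them unequally, so that stays open. Lymph node tissue in the knockout samples stays open, since the B cell genes, with a median of 0.35 (0.10 to 0.60 with each library left out), all lay under 5 CPM, as does the hypothesis of a change in both the number and the state of macrophages, which was not tested and would need counted and sorted cells.

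Genes near Mpst on chromosome 15 changed in both directions. Within 1 Mb of Mpst, 6 of 42 tested genes (14.3%) were called, namely Baiap2l2, Csf2rb2, Gcat, Ift27, Kctd17 and Txn2, against 7.38% of the other genes (odds ratio 2.09, 95% interval 0.719 to 5.03). Variants linked to the allele, or a local effect of it, could not be told from chance by this count (Fisher's exact test, two-sided p = 0.126), since the interval of the odds ratio holds both 1 and values above 2. Gcat and Txn2 encode mitochondrial proteins and lie in this window, so for them a linked effect and an effect of losing MPST cannot be told apart.

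Malat1 stood at 1414 ± 406 CPM in wild type and 286 ± 80.2 CPM in knockout (SD, n = 3), and Kcnq1ot1, another nuclear RNA, at 18.3 ± 4.78 and 6.79 ± 3.10 CPM (edgeR adjusted p = 0.0444). Neat1, also nuclear, stood at 2105 ± 898 and 1542 ± 459 CPM (edgeR adjusted p = 0.381). Acta1, skeletal muscle actin, reached 179 CPM in wild-type replicate 2 and 405 CPM in knockout replicate 3, and Ckm, muscle creatine kinase, 68.1 and 120 CPM.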
